A study of Caenorhabditis elegans with 4 samples.

How the data were processed

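Chromatin from Caenorhabditis elegans larvae of the L3 stage (the third of 4 larval stages) was examined for binding of MAB-5, a homeodomain protein of the Hox family. The animals were of strain OP26, which carries a mab-5 transgene per the labels, and the immunoprecipitation used an antibody against GFP. Per the labels' protocols, larvae were cross-linked in 2% formaldehyde for 30 minutes and chromatin was sheared to 200 to 800 bp. The 4 libraries were 2 GFP ChIP libraries and 2 Input libraries, and the labels state that each Input came from the same preparation as its ChIP.

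Each library came with one line per 27-base read. According to the description that the authors deposited with the series, these are ELAND output with up to 2 mismatches, and every read is kept with its match class and its number of genome matches, a value that is not an abundance. The ELAND version and the genome build are not given in the sources used here. Each ChIP library also came with a list of peaks that the authors called with PeakSeq, one list per ChIP library against its Input, at a q-value of at most 0.05. In those lists the authors deposited the count of ChIP tags per peak, the Input tags normalized to the ChIP library as a score rounded to whole numbers, the ratio of the pair, their difference, and the Benjamini-Hochberg q-value of a binomial test. Their ratio and q-value were used only to describe and rank peaks within a list.

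Reads with 1 best match (ELAND classes U0, U1 and U2) on the 6 nuclear chromosomes were analysed. Each read was moved 100 bp into its fragment. Library sizes were scaled so that the median 10000 bp bin (bins with at least 20 reads in each library) had the same CPM in all 4 libraries. The scaled sizes were 0.983, 1.02, 0.955 and 1.05 times the total for GFP ChIP replicate 1, Input replicate 1, GFP ChIP replicate 2 and Input replicate 2. Reads at a position and strand already occupied by another read of the library made up 53.2%, 12.6%, 12.3% and 3.71% of these libraries, in that order. Such reads may be copies of 1 fragment, so the intervals given for shares of reads cover counting error only.

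Peaks of both lists were called shared when they overlapped by at least 1 bp, and overlapping peaks were merged into shared regions. The overlap was compared with 1000 random placements of the second list on the same chromosomes. Enrichment was log2((ChIP CPM + 0.5)/(Input CPM + 0.5)) within a replicate, so it understates the change of regions with few reads. Windows of 500 bp with a mean of at least 10 reads were tested with limma 3.58.1 (R 4.3.3, trend) on log2(CPM + 0.5), 2 ChIP against 2 Input libraries, with Benjamini-Hochberg adjusted p under 0.05. The test was run on simulated data first. Of 100 windows changed 4-fold among 70362 it recovered 93%, of 100 changed 2-fold it recovered 4%, and 8 of 105 calls were false. The simulated counts were negative binomial with size 50 around the mean Input profile. Changes were planted only in windows with a mean of at least 10 Input reads. The real libraries may vary more, so these rates hold for the simulation only. The replicate number pairs ChIP and Input through the shared preparation, but the deviations of same-numbered libraries from their group means had a Pearson r of -0.0123 across windows, and a fit with replicate as a block was an alternative. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

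No sequence or annotation of the files' genome build was used. The one reference table, of assembly WBcel235, served only for gene names, chromosomes and neighbours. To name genes in the coordinates of the files, a partial genome sequence was rebuilt from reads with an exact single match. It held 65.1%, 65.1%, 66.3%, 62.6%, 63.0% and 68.2% of chromosomes I, II, III, IV, V and X, and 0.114% to 0.129% of repeated base calls on these chromosomes conflicted. Mature microRNA sequences (98 searched, 74 genes placed) were placed where they matched exactly and once, with at least 16 rebuilt bases, on the chromosome the table gives. Protein domains (29 queries) were searched with tblastn (BLAST+ 2.17.0). This placed the 6 Hox genes, with at least 38 bits and named by their order on chromosome III, and 17 other genes with at least 50 bits and 5 bits more than any rival. The queries were written from memory and chosen after the files had been opened and some peaks near Hox genes had been seen. A gene placed by domain marks the domain, not the gene's ends.

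Because gene ends were not known, the position of peaks relative to genes was not analysed here, and of the 29 gene lists fixed beforehand only the members placed by sequence could be examined. A microRNA locus (placed microRNAs of 1 strand within 2000 bp of each other) counted as bound when a shared region lay between 2000 bp upstream of the mature sequence and its end. A gene placed by domain counted as bound with a shared region within 5000 bp. Both were compared with 10000 random lists of rebuilt positions on the same chromosomes (two-sided permutation p, adjusted over the 3 sets that could be tested). These random lists replaced the planned lists matched on gene length.

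Each of 6 motifs was counted in the central 200 bp of a shared region and in 200 bp windows starting 400 bp to each side, per kb of rebuilt sequence. The planned sign test needs complete sequence. It was replaced by 100000 random draws that assign each match to centre or flank in proportion to the rebuilt sequence there (two-sided, adjusted over 6 motifs). At random places 3 of 60 such tests gave p under 0.05, and 60 of 60 did after matches were planted in 10% of the regions. The Input reads in 40000 bp centred on the mab-5 homeodomain were compared with the median bin of that width on chromosome III.

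The regions named in the text were the 25 shared regions with the largest mean log2 ratio among those with at least 20 ChIP reads in each replicate and a log2 ratio above 1 in both. In addition come mab-5 and every other Hox gene, and at most 4 bound members of each fixed list. The rule names regions by the nearest gene end, which was not known, so they are given by position. Alternatives changed the overlap, window, pseudocount, filter, scaling, test, pairing, repeated reads and read shift, or left out a library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. All coordinates are those of the deposited files.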

Results

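MAB-5 is a Hox protein known to pattern the posterior body of C. elegans and to direct neuroblast migration. Sites enriched by its GFP ChIP were mapped in L3 larvae of the transgenic strain OP26. None of the 4 libraries was a ChIP from animals without the transgene or with a control antibody. Enrichment over Input alone therefore does not separate sites of MAB-5 from others that the ChIP may recover. Below, bound means enriched in this sense. Each of 2 GFP ChIP libraries was set beside the Input library of its own preparation. GFP ChIP replicate 1 held 2878305 reads, of which 1543390 had 1 best match on a nuclear chromosome. Input replicate 1 held 1069347 such reads of 2766703. GFP ChIP replicate 2 held 1958220 of 7656043, and Input replicate 2 held 2430585 of 6576488. Reads that matched nowhere made up 36.1%, 48.4%, 69.5% and 54.2% of the libraries in that order. In GFP ChIP replicate 1, 53.2% of the matched reads repeated the position and strand of another read, and only 721745 positions were distinct.

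The first question was which sites both ChIP libraries recovered. The authors' list held 9840 peaks for replicate 1 and 1946 for replicate 2, with median widths of 265 and 401 bp. Of the replicate 2 peaks, 1546 (79.4%) overlapped a replicate 1 peak. Random placement gave 161 on average and at most 211 over 1000 placements. The observed overlap was 9.61 times that mean (one-sided permutation p = 0.001, the smallest these placements can give). Placements could fall anywhere on a chromosome, also where reads rarely match once. The mean may therefore be too low and the fold too high. Of the replicate 1 peaks, 1600 (16.3%) overlapped a replicate 2 peak. Merging gave 1538 shared regions. They were densest on chromosome III, with 30.9 per Mb of rebuilt sequence, and sparsest on V, with 16.4. When each chromosome was divided into 3 equal parts, the central part of V held 1.84 times the density of the outer parts, and this ratio was 0.969 on X. When the longer list was reduced to the 1946 peaks with the smallest q-value, 901 replicate 2 peaks still had a partner.

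The size of the enrichment was measured at the shared regions. They were selected as peaks called in both replicates from these same reads, so a ratio above that of random places follows from the selection. The median log2 ChIP/Input ratio was 1.85 in replicate 1 and 1.91 in replicate 2, a mean of 1.88 ± 0.04 (SD, n = 2), and 1332 of the 1538 regions (86.6%) had a log2 ratio above 1 in both. Random places of the same widths had medians of -0.02 and -0.09. The regions covered 1.05% of the chromosomes and held 7.59% of the reads of GFP ChIP replicate 1 (Wilson 95% interval 7.55% to 7.64%) and 7.82% of those of GFP ChIP replicate 2 (7.78% to 7.86%). The Input libraries had 2.46% (2.43% to 2.49%) and 2.40% (2.38% to 2.42%) of their reads there. Across regions the 2 replicates' ratios correlated weakly (Pearson r = 0.19). Regions are not independent replicates.

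**Figure D1:**
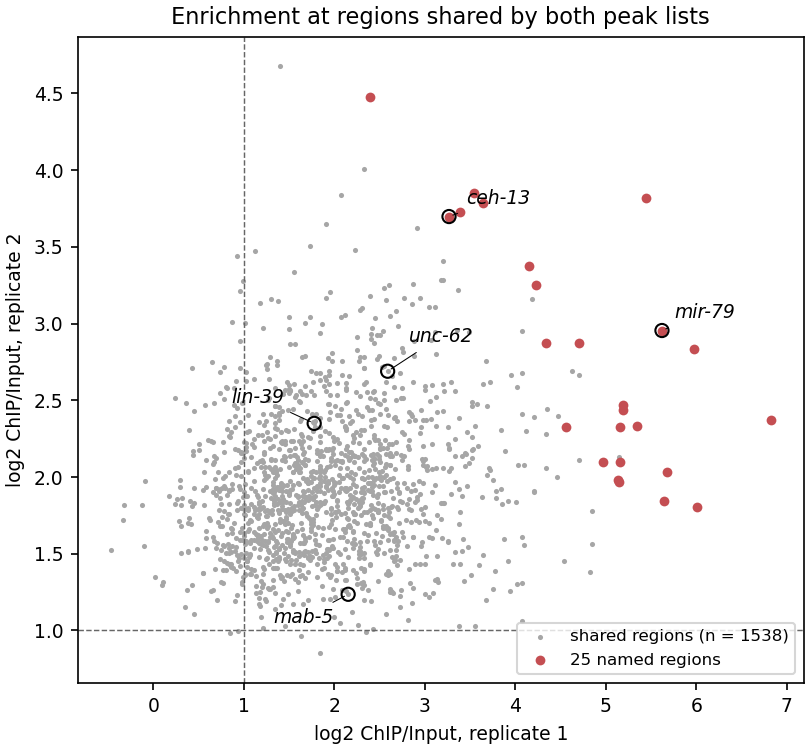
Log2 ChIP/Input ratio of each shared region in replicate 1 (x axis) and replicate 2 (y axis), with the 25 named regions in red and the regions nearest 5 genes circled. Dashed lines mark a log2 ratio of 1, and 1332 of the 1538 regions lie above both lines.

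Across the genome, 1832 of 58022 tested windows were higher in ChIP than in Input and 5 were lower (limma, adjusted p under 0.05). Over the tested windows the log2 CPM of the 2 ChIP libraries correlated with a Pearson r of 0.32. For the 2 Input libraries this r was only 0.046. The 2 replicates' log2 ChIP/Input ratios correlated with an r of 0.15. The higher windows had a median log2 difference of 1.98, and 1196 of them (65.3%) overlapped a shared region, against 5.87% of all tested windows. The regions were called from the same reads, so a larger share among higher windows follows from that and is no separate evidence. The 5 lower windows, named because they were few and after their values were seen, had log2 differences between -2.34 and -2.05, and GFP ChIP replicate 1 had 0 to 3 reads in each against 17 to 44 in Input replicate 1. They started at I:9619001, III:884501, V:4732501, V:18705501 and X:1409501. In replicate 2 the ChIP and Input reads were 29 and 31 at I:9619001, 21 and 30 at III:884501, 18 and 22 at V:4732501, 10 and 22 at V:18705501 and 12 and 20 at X:1409501. At I:9619001 and V:4732501 GFP ChIP replicate 2 was above its Input after scaling. Without either ChIP library limma called 0 windows, with 4045 windows at an unadjusted p under 0.05 without GFP ChIP replicate 1 and 7084 without GFP ChIP replicate 2. Such a fit has 1 residual degree of freedom, but so do the fits without an Input library, which still called windows. Without a ChIP library the spread within groups comes from the Input libraries alone. The lost calls therefore do not show that the signal needed both ChIP libraries, and their cause was not tested. In the full comparison 7178 windows had an unadjusted p under 0.05, and limma voom called 471 higher and 0 lower, with 7018 at an unadjusted p under 0.05. Without Input replicate 1 limma called 977 higher and 0 lower windows (4669 at an unadjusted p under 0.05), and without Input replicate 2 it called 2133 higher and 52 lower.

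The strongest named region was IV:13682620-13683445, with log2 ratios of 5.44 in replicate 1 and 3.82 in replicate 2 (mean 4.63 ± 1.15, SD, n = 2). It ranked 7th and 3rd in the authors' lists. It opened a group of 8 shared regions within 40 kb of chromosome IV, where the chromosome's average density gives 0.654, and their mean log2 ratios ran from 1.91 to 4.63. This stretch was singled out after the values were seen. Other regions of the group were IV:13689282-13689888 (3.74 ± 0.69), IV:13694617-13694953 (3.72 ± 0.10) and IV:13721024-13721301 (3.66 ± 1.37). The next in rank were I:6506537-6506950 (4.60 ± 3.15) and IV:11174808-11175149 (4.41 ± 2.22). The 25 regions had mean log2 ratios from 3.44 to 4.63, and 9 lay on I, 7 on IV, 3 each on II and V, 2 on III and 1 on X. Input replicate 1 had no read in 10 of them and at most 1 read in 15, so their order rested on the pseudocount and on replicate 1. Ranked on replicate 2 alone, 8 of the 25 stayed in the top 25, and by the mean rank in the authors' lists 5 did. Only 2 of the 25 lay within 10 kb of a gene placed by sequence, and these are described with ceh-13 and mir-79.

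The Hox genes were examined next, since Hox proteins are known to regulate one another. Of the 6 Hox genes, 3 had a shared region within 5 kb of the homeodomain, against 1.25 ± 1.00 in random lists (two-sided permutation p = 0.22, adjusted p = 0.33). The strongest lay 1917 bp from ceh-13, the anterior Hox gene of the labial type. This region, III:7554256-7555242, had log2 ratios of 3.27 and 3.70 (mean 3.48 ± 0.30, SD, n = 2), and its window from III:7554501 was called (log2 3.61, adjusted p = 1.99e-09, limma). Next to lin-39, the Hox gene of the midbody and vulva, III:7534334-7535036 had a mean of 2.06 ± 0.40. Its best window had a log2 difference of 2.22 (limma adjusted p = 0.00154), and 1 of its 3 windows was called. At ceh-13, lin-39 and the genes below, the regions were called from the same reads. A small p in a window picked within such a region follows in part from that and is no separate evidence. The 27.5 kb from the lin-39 to the ceh-13 homeodomain held 6 shared regions, where the average density of chromosome III gives 0.563. One of them, III:7544157-7544495, named after its values were seen, lay 501 bp from mir-231, on the downstream side of that microRNA, with a mean of 2.46 ± 0.07.

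At mab-5 itself, III:7778396-7781110 reached into the homeodomain (III:7778310-7778447), with log2 ratios of 2.15 and 1.24 (mean 1.69 ± 0.65, SD, n = 2; limma adjusted p = 0.00035 for its best window). A further region in the interval from mab-5 to egl-5, III:7783747-7784662, had ratios of 3.32 and 1.43, and III:7781379-7782592 had 1.84 and 0.85. The Input reads were raised in this stretch as well, and the ratios are relative to them. No shared region and no peak of either list lay within 5 kb of the homeodomains of egl-5, which acts in the tail, or of the posterior genes php-3 and nob-1.

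**Figure D2:**
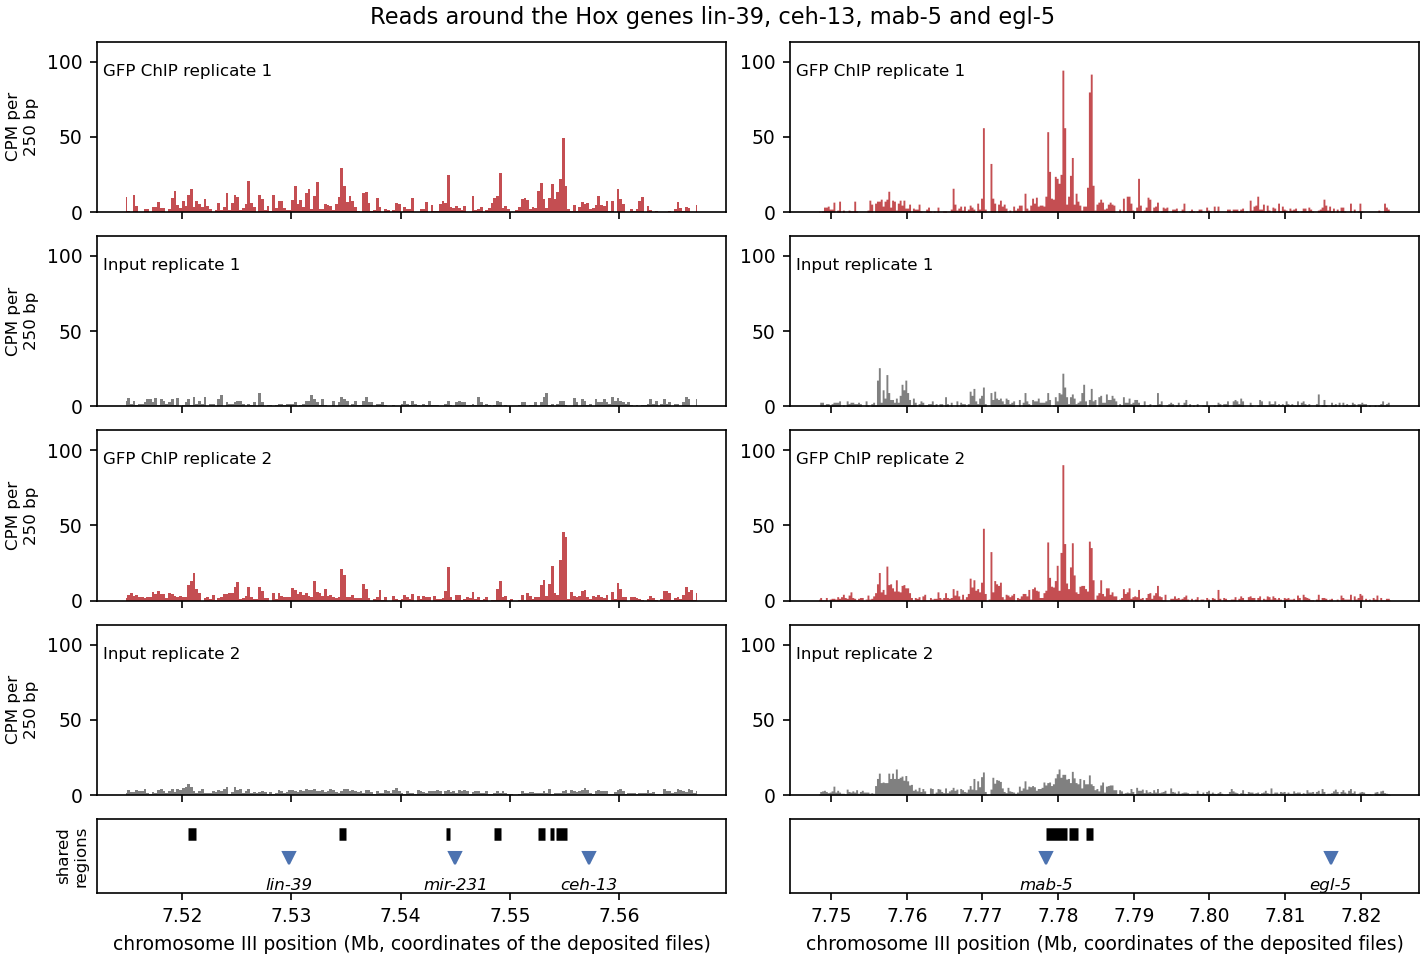
Reads per 250 bp bin in CPM (y axis, one scale for all panels) along chromosome III around lin-39, mir-231 and ceh-13 (left) and around mab-5 and egl-5 (right), for the 2 ChIP libraries (red) and 2 Input libraries (grey). Black bars are shared regions and triangles the sequences by which genes were placed. The ChIP signal next to ceh-13 and mab-5 stands above the Input of the same replicate.

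Among the partners of Hox proteins, unc-62, which encodes a Meis-type homeodomain cofactor, had 2 shared regions within 5 kb of its homeodomain. The region V:4506661-4508547 lay 763 bp from it, with log2 ratios of 2.59 and 2.69 (mean 2.64 ± 0.07, SD, n = 2). It ranked 1st in the authors' replicate 1 list and 4th in their replicate 2 list, and its best window had a log2 difference of 3.40 (limma adjusted p = 1.44e-09). At ceh-20, the Pbx-type cofactor, III:6978591-6979400 had ratios of 0.45 and 1.93, and limma called none of its windows (smallest adjusted p = 0.0943). At snb-1, the synaptobrevin gene of neurons, V:6658266-6659163 had a mean of 1.83 ± 0.20 (limma adjusted p = 0.0116 for its best window). These were the 3 of the 17 other genes placed by domain with a shared region within 5 kb, against 2.91 ± 1.55 in random lists (two-sided permutation p = 1, adjusted p = 1). The remaining 14, among them hlh-8, hlh-1, pal-1, vab-7, elt-1, pha-4, lin-11, let-60 and pop-1, had no shared region in reach. Peaks of replicate 1 lay within 5 kb of some of them, with 5 at elt-1, 3 at daf-16, 2 at let-60 and 1 each at hlh-1, vab-7, unc-120, daf-2 and ceh-22.

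Shared regions lay near microRNA genes more often than near random positions. Of 63 microRNA loci, 9 had a shared region in reach, against 3.27 ± 1.76 in random lists (2.75-fold, two-sided permutation p = 0.012, adjusted p = 0.036). All replicate 1 peaks gave 25 loci (permutation p = 0.0088) and all replicate 2 peaks 9 (permutation p = 0.03). Random positions are not matched to gene starts, so the comparison does not separate microRNA genes from other genes. The largest ratio was at I:9330769-9331112, 1885 bp upstream of mir-79, with a mean log2 ratio of 4.29 ± 1.88 (SD, n = 2), and Input replicate 1 had 1 read there. Next came mir-62 (X:12690288-12690670, 2.21 ± 0.32), mir-2 (I:9372744-9373797, 1.59 ± 0.11) and mir-34 (X:2970803-2971961, 1.58 ± 0.06). Their best windows had limma adjusted p of 1.11e-08, 0.0267, 0.0221 and 0.00697. Per the reference table, mir-62 lies within the protein-coding gene ugt-50 and mir-2 within ppfr-1, while mir-79 and mir-34 lie in none. A region at such a microRNA may belong to the host gene instead.

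Members of the heterochronic list, genes that time the larval stages, were also among the bound microRNAs. The let-7 relatives mir-48 and mir-241 shared the region V:14366055-14367185, with log2 ratios of 0.29 and 1.93. Within it limma called no window (smallest adjusted p = 0.102). In all, 2 shared regions lay in reach of mir-241. This one was the nearest, and the values of the other are not given here. The placed members lin-4, let-7 and mir-84 had no shared region in reach, while 2 replicate 1 peaks lay in reach of lin-4 and 1 in reach of let-7. No replicate 1 peak by itself lay in reach of mir-48, whose region was in reach through its replicate 2 part. The region nearest to let-7 lay 2651 bp from it.

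**Figure D3:**
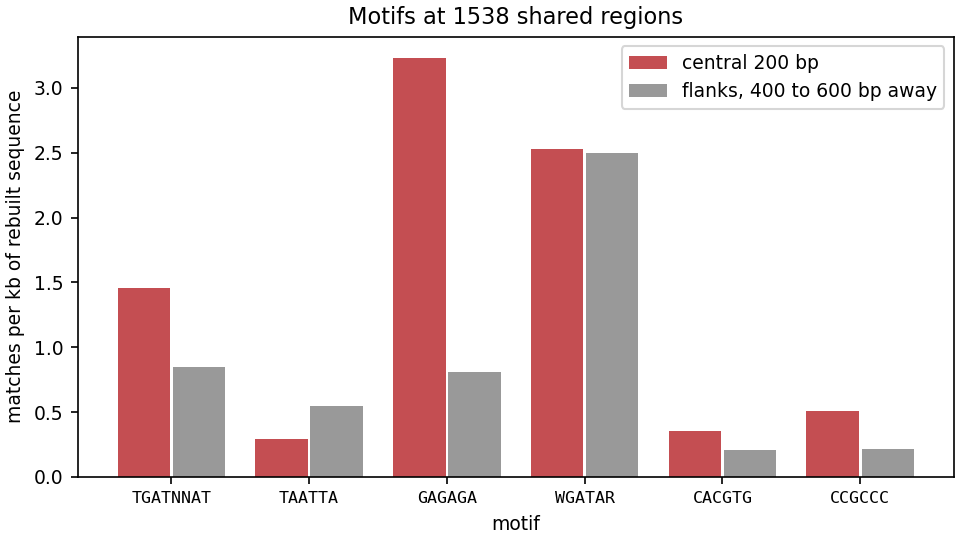
Matches per kb of rebuilt sequence (y axis) for the 6 motifs fixed beforehand (x axis), in the central 200 bp of the 1538 shared regions (red) and in flanks that start 400 bp to each side (grey). GAGAGA reached 3.23 per kb in the centres against 0.812 in the flanks.

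Sequence motifs differed between the centres and flanks of the shared regions. TGATNNAT is the type of site at which Hox and Pbx proteins bind together. It occurred at 1.46 per kb in the centres and 0.848 in the flanks (1.72-fold, adjusted p = 3e-05, 100000 random draws). Of the regions, 22.8% had a match in the rebuilt part of their central 200 bp. The same letters reversed occurred at 0.489 times the flank rate. TAATTA, the core bound by many homeodomains alone, was less frequent in the centres, at 0.292 against 0.549 per kb (0.532-fold, adjusted p = 3e-05). GAGAGA, the GAGA-type repeat, was the most enriched, at 3.23 against 0.812 per kb (3.98-fold, adjusted p = 3e-05), and its reversed form gave 4.02-fold. That form, AGAGAG, is the same repeat read from its next base, so it is no control for this motif. CACGTG (1.72-fold, adjusted p = 0.000168) and CCGCCC (2.40-fold, adjusted p = 3e-05) were also enriched, while their reversed forms gave 1.80-fold and 2.87-fold. The GATA-type site WGATAR did not pass the test (1.01-fold, adjusted p = 0.719), and its reversed form gave 1.08-fold. The raw p of the 4 smallest was 2e-05, the smallest these draws can give. The draws placed every match by itself, so these p-values do not cover the clustering of matches within regions. GAGAGA, for instance, had 941 centre matches in 596 regions. The centres had a GC content of 42.9% and the flanks 36.7%.

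Because the strain carries a mab-5 transgene, the Input reads around mab-5 were compared with the rest of chromosome III. In the 40 kb centred on the homeodomain, Input replicate 1 had 1.56 times the reads of the median bin, which ranked 4th among 344 bins. Input replicate 2 had 2.15 times, and ranked 1st. The mean log2 ratio was 0.87 ± 0.33 (SD, n = 2), and GFP ChIP replicates 1 and 2 had 2.99 and 2.71 times the median bin. In 10 kb the Input ratios were 2.01 and 3.13. The stretch around mab-5 in which the running mean over 5 bins of 2 kb was at least 1.3 times the median bin in both Input libraries ran from III:7766001 to III:7790000, and the mean there was 1.97 and 2.56 times the median.

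**Figure D4:**
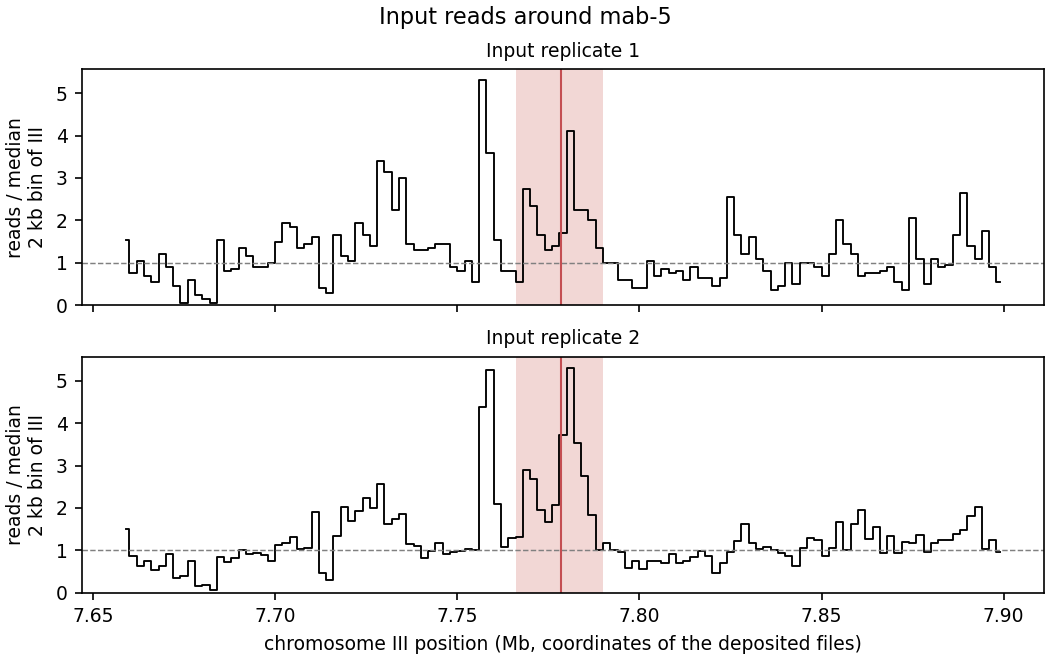
Input reads per 2 kb bin divided by the median 2 kb bin of chromosome III (y axis) along the chromosome around mab-5, in replicate 1 (top) and replicate 2 (bottom). The red line marks the mab-5 homeodomain, the shaded stretch of 24 kb had a running mean over 5 bins of at least 1.3 times the median in both, and the dashed line is the median.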

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

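The test of the codons of GFP-coding reads, and the searches of unmatched reads, were chosen only after results they bear on were seen.

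Reads that ELAND matched nowhere, which no comparison above used, held signals that were higher in the ChIP libraries than in either Input. Reads coding for 8 residues of GFP in 1 frame made up 7.64 RPM, relative to all reads of the library, in GFP ChIP replicate 1 and 12.1 RPM in GFP ChIP replicate 2, against at most 2.89 RPM in the Input libraries. In GFP ChIP replicate 1 these were 22 reads, 13 of them distinct (95% Poisson interval 4.79 to 11.6 RPM). Input replicate 1 had 8, all distinct (1.25 to 5.70 RPM). These intervals overlap, so the difference between these libraries may be counting error. Reads within 2 mismatches of the primate Alu repeat made up 1703 and 3810 RPM, against at most 53.1 RPM. Reads that began with the sequencing adapter made up 0.147% and 5.47%, against at most 0.00271%. A search with the GFP protein reversed gave 0, 1, 0 and 0 reads in GFP ChIP 1, Input 1, GFP ChIP 2 and Input 2.

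In GFP ChIP replicate 2, 61 of 93 GFP-coding reads had at least 7 of 8 codons ending in G or C, against 5 of 46 in the other libraries pooled (Fisher's exact test, two-sided p = 6.04e-10, which covers counting error only and takes repeated reads as independent). Counted once per distinct sequence, 53 of 83 had such codons in GFP ChIP replicate 2, against 3 of 13 in GFP ChIP replicate 1, 1 of 8 in Input replicate 1 and 0 of 16 in Input replicate 2. This argues against the tag of strain OP26 as the only origin of these reads, since Input replicate 2 came from the same preparation. DNA from human cells that carried another GFP construct is a candidate explanation, because Alu-like reads were 2.24 times as frequent in this library as in GFP ChIP replicate 1, the highest of the other libraries. That test does not tie the GFP reads to the Alu-like reads, and another origin was not tested.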

How the results depend on the processing

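The ranking of named regions with 1 read per position and strand (22 of the 25 in common) was chosen after seeing the data. Of 77 values under alternatives, 50 stayed the same and 25 moved. Counts were taken as the same within a fixed fold of the main count. Other values had to stay within the spread or on their side of the threshold. Of the motif values 22 stayed the same, 2 passed the test only under the alternative, and none turned direction. The overlap fell from 1546 peaks to 765 of 973 in the 50% of each list with the smallest q-values and to 901 with the longer list shortened, both of which compare fewer peaks. The median enrichment of 1.88 moved to 1.79 with scaling by total reads and 1.92 with a pseudocount of 0.1. With 1 read per position and strand the share of reads in shared regions was 7.86% (GFP ChIP 1), 2.54% (Input 1) and 7.46% (GFP ChIP 2). The Input ratio at mab-5 rose to 1.33 (log2) in 10 kb. By the authors' score 5 named regions stayed in the top 25. With either replicate left out 8 to 17 did. WGATAR passed in all replicate 1 peaks (1.07-fold, adjusted p = 0.00012) and all replicate 2 peaks (1.23-fold, adjusted p = 2e-05, the smallest the draws can give). The 1832 higher windows became 536 at 1000 bp, 246 without a filter, 471 with limma voom and 2896 with 1 read per position and strand. The 5 lower became 10 at 1000 bp, 8 with scaling by total reads, and 0 without a filter and with limma voom. Leaving out 1 library gave 0 to 2133 higher and 0 to 52 lower windows. Both counts were 0 without GFP ChIP replicate 1 or 2. They were 977 and 0 without Input replicate 1, and 2133 and 52 without Input replicate 2. A lone library was assumed to vary like the other group. The replicate block gave 2204 higher and 5 lower windows, and changed no other call since no other test had it. The cause was not tested where none is named. With 2 libraries per group at this depth, simulated 2-fold changes were recovered in 4% of cases, and depth and library number were not tested apart. Peak positions relative to genes, with their alternatives, were not run.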

Other observations

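The test of extra mab-5 copies, the test of peak significance, the scan of 6-base words and the ranking of 40 kb bins were chosen or reworked only after results they bear on were seen.

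Among 2508 bins of 40 kb, the highest count was 7 regions, reached at II:6800001-6840000, at III:7520001-7560000, which holds lin-39 and ceh-13, and at IV:13680001-13720000, which holds the strongest named region. The bins II:11720001-11760000, V:4480001-4520000, which holds unc-62, and X:11440001-11480000 had 6 each.

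Other microRNA genes with a shared region over or upstream of the mature sequence were mir-52 (mean log2 ratio 1.46 ± 0.24, SD, n = 2), mir-71 (1.10 ± 0.52), mir-90 (1.56 ± 0.84) and the group mir-54, mir-55 and mir-56 (1.58 ± 0.34). All but mir-52 lie within a protein-coding gene of the reference table. The hosts are ppfr-1 for mir-71, K01F9.2 for mir-90 and F09A5.3 for the group, and the regions may belong to them. A scan of 2075 words of 6 bases found 276 more frequent and 202 less frequent in the centres of shared regions than in their flanks (Bonferroni). GAGAGA was 4.24-fold, CACACA 3.41-fold, ACGCAG 5.03-fold and GCGCGC 6.83-fold as frequent, while AAAATT had 0.471-fold. The centres were richer in GC, and the scan did not correct for that. It also counted overlapping occurrences one by one and pooled them over regions. A repeat tract thus counted many times and under several words, so the counts of words that passed may be too high.

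The replicate 1 list was 5.06 times as long as the replicate 2 list. Peaks found in replicate 1 alone kept a median log2 ratio of 1.71 with 1 read per position and strand, which argues against repeated reads as the source of the ratios, although the peaks were selected on these reads. Whether repeated reads raised the significance of peaks stays open: 28.3% of replicate 1 peaks passed, with 1 read per position and strand, the binomial p that 50% passed with all reads, between the bounds set, and the same measure gave 38.4% in replicate 2. A first version of that test, whose threshold every peak passed, was void and was replaced. The same peaks had a median log2 ratio of 0.81 in replicate 2, with 75.7% above 0 against at most 48.4% in 1000 random placements (median ratio 0), consistent with sites also bound there but under the threshold, and no biological explanation was tested.

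Extra copies of mab-5 sequence in strain OP26 may account for the raised Input around the gene. The lower of the Input libraries had 1.56 times the median 40 kb bin, and 1.55 times with 1 read per position and strand, which argues against repeated reads. The GC content of the 40 kb was 35.0%. Of the chromosome III bins within 1 percentage point of it, 0% had as many Input reads in both libraries. That share could not be otherwise, since the mab-5 stretch ranked 1st among 344 bins in Input replicate 2. It therefore does not count against base composition. The highest of these bins reached 1.16 times the median, so bins of like GC content were not raised as far. The rise was uneven, with 5.30 and 4.39 times the median in the 2 kb from III:7756001, 0.80 and 1.08 times from III:7762001, and 4.10 and 5.31 times from III:7780001, and it was not limited to the gene, with 3.40 and 2.57 times from III:7728001 and 3.00 and 1.86 times from III:7734001. Which parts, if any, are present in extra copies, or whether chromatin state adds to the rise, stays open.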
